A study of Mus musculus with 21 samples.

How the data were processed

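RNA sequencing of primary mouse brain microglia was deposited as 2 tables, each with its own normalization. The aging table held 12 libraries, 3 each from young wild type, young Trem1-/-, aged wild type and aged Trem1-/-. The 5XFAD table held 9 libraries from adult mice, 3 each from wild type, 5XFAD and 5XFAD Trem1+/-. 5XFAD mice carry transgenes of familial Alzheimer's disease and develop amyloid plaques. Per the labels, total RNA was extracted with the RNeasy mini plus kit and libraries were made with the NEBNext Ultra RNA kit. The labels gave no isolation protocol, no sort gate and no RNA selection step. They did not say that the libraries of a group came from separate animals, so every p-value below measures only the spread between samples.

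Per the labels, the authors trimmed reads with fastp, aligned them to GRCm38 with HISAT2 2.0.5, counted them per gene with featureCounts 1.5.0-p3 and used DESeq2 1.20.0. The annotation release and the strandedness were not stated. The deposited per-library columns and the mean column held a signal, counts divided by a size factor. Dividing each column by the value of 1 read gave whole numbers within 0.05 read for at least 99.9956% of nonzero values, and these recovered reads gave the depths. The deposited tables also held the authors' log2 fold change, its standard error, the Wald statistic as a score, and a p-value with its adjusted p-value. In the aging table those statistics compared young wild type with aged Trem1-/-, with 441 genes higher and 1045 lower of 20305 with an adjusted p. In the 5XFAD table they compared wild type with 5XFAD, with 197 genes higher and 655 lower of 20098. In both, a positive deposited value means higher in wild type, opposite to the directions used below. A column of marked genes in the 5XFAD table held 557 entries, of which 550 matched the gene of their own line, and was not used.

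Each table listed 54532 gene symbols, of which 53749 matched GENCODE M21, the source of positions and gene types. Genes with a mean normalized count of at least 10 over a table were tested: 16086 in the aging table and 17025 in the 5XFAD table. The test was limma 3.58.1 (R 4.3.3, trend and robust) on log2(normalized count + 1), with all groups of a table in 1 fit and a Benjamini-Hochberg adjusted p under 0.05 as the threshold. Fold changes below are therefore differences of mean log2(normalized count + 1), with the standard error of the fit. The smallest p that an exact permutation test of 3 against 3 libraries allows is 0.1, so no such test was used to call genes. Its p is given only for Trem1 relative to markers of other cells. Where all libraries of a group were at 0, the fold is given as a bound against a floor of 3 reads in each library.

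A set of 33 gene lists with 711 genes was fixed before the data were examined, as were the comparisons, the test, the rule for named genes and most alternatives. The lists covered microglial states, innate signalling, metabolism, protein synthesis, lysosomes, proliferation, handling stress and markers of other cell types. Lists with at least 3 measured members were tested with camera (limma) at a preset correlation of 0.01, adjusted over the lists of a comparison. The same lists were tested with an estimated correlation and with fry. Named genes were Trem1, the 8 largest rises and 8 largest falls among genes past the threshold whose groups did not overlap and whose higher group had a mean of at least 50, and up to 4 genes of each called list or list with 3 changed members. For comparisons with no gene past the threshold, and for the interaction, the 5 genes with the smallest p were taken. Some genes that this rule names are not reported here.

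A floor of 3 reads equalled 2.06 to 4.51 normalized counts in the aging table and 2.26 to 4.36 in the 5XFAD table. These floors cover counting error only, since reads without molecular identifiers are not independent molecules. No pair of replicates was a duplicate: chi-square per degree of freedom between replicates of a group was 11.9 to 41.7. Residual correlations of libraries of different groups with the same replicate number had a median of 0.0119 in the aging table and 0.0116 in the 5XFAD table, although 7 of 9 libraries in the 5XFAD table were closest to a library of their own number and replicate 1 was the highest library of all 3 groups there for Ttr, Kl, Folr1 and Clic6. No block was used, and a replicate block was among the alternatives.

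The test was checked on simulated data with the depth and spread of each table. The changed genes and the lists were drawn from genes with a mean of at least 50. Recovery of the lower genes among those tested was therefore not measured. In the aging layout 13.4% of genes changed 1.5-fold, 56.7% changed 2-fold and 89.4% changed 4-fold were called, with 5 unchanged genes among the calls. In the 5XFAD layout these were 7.46%, 43.3% and 77.3%, with 2 unchanged genes. A list of 25 genes moved 1.3-fold was called in both layouts and 0 of 32 unmoved lists was called. Genes were simulated as independent of each other, so this check does not cover lists of correlated genes.

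Alternatives fixed in advance were quantile normalization, edgeR 4.0.16 and DESeq2 1.42.0 on the recovered reads, no filter, a mean of at least 50, pseudocounts of 0.5 and 5, a replicate block, limma without trend and robust, a fold of at least 2, only the groups compared, fry, an estimated correlation, and each library left out in turn. Alternatives chosen after seeing the data were the mean of the neutrophil and monocyte markers as a covariate in the aging table, the mean of the ependyma and choroid plexus markers as a covariate in the 5XFAD table, and the fit without the library farthest from the others. Relations between comparisons that share a group were set beside 100 simulations of unchanged groups. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for reading the tables and drawing.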

Results

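Gene expression was measured by RNA sequencing in primary mouse brain microglia, to ask how deletion of Trem1 changes microglial expression during aging and in 5XFAD mice. The aging table compared young and aged wild type with young and aged Trem1-/-, and the 5XFAD table compared adult wild type, 5XFAD and 5XFAD Trem1+/-, each with n = 3 libraries. Young and aged are given in the labels as words without months. Libraries held 8600878 to 19411434 reads on genes in the aging table and 9264999 to 18698707 in the 5XFAD table. Changes are log2 differences ± SE from limma, with adjusted p over all genes tested, and a list's call is from camera. Genes named as risen or fallen kept their call with each library left out, unless the paragraph says otherwise.

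Trem1 encodes a myeloid cell-surface receptor that signals through DAP12 and amplifies inflammatory responses; it lies on chromosome 17 at 48232768 to 48246924 (GRCm38, plus strand, ENSMUSG00000042265.13). Its normalized count was 13.9 ± 9.83 (SD, n = 3) in young wild type and 92.9 ± 5.95 in the libraries labelled young Trem1-/-, the reverse of what the labels alone would give. Aged wild type had 231 ± 40.8, and the libraries labelled aged Trem1-/- had 164 ± 68.9. The lowest library labelled Trem1-/- had 85 Trem1 reads against a floor of 3 reads, and the lowest young wild-type library had 7. In the 5XFAD table Trem1 was at 31.0 ± 31.4 in wild type, 27.5 ± 12.2 in 5XFAD and 27.2 ± 10.2 in 5XFAD labelled Trem1+/-. Without replicate 1 the mean was 8.19 in young wild type and 15.1 in adult wild type. Adult wild type replicate 2 had no Trem1 reads, and without it the mean was 46.4. The labels do not say which part of the gene is deleted, and the tables hold no counts per exon. Genotypes are therefore given below as labelled, and every direction of a genotype comparison rests on those labels.

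**Figure D1:**
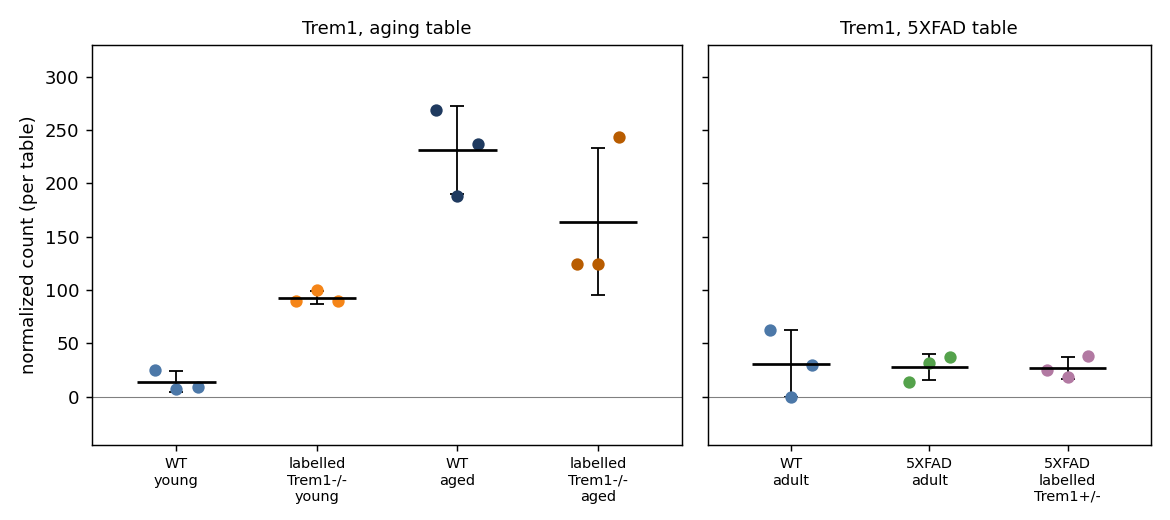
Normalized count of Trem1 in each library (points), with the group mean (line) and SD (bar), n = 3 per group; the scale of each table is its own. The libraries labelled young Trem1-/- sit above the young wild-type libraries, and no library labelled Trem1-/- is at 0. Adult wild type replicate 2 is at 0.

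The first comparison asked what aging did in wild-type microglia. Aged wild-type libraries carried higher levels of neutrophil and monocyte transcripts than young ones. Of 15 measured neutrophil markers, 13 rose, 14 when adjusted over the list alone, with a median log2 change of 3.03. Among them, the secreted neutrophil protein Retnlg rose by 3.33 ± 0.26 (adjusted p = 7.8e-07), the chemokine receptor Cxcr2 by 3.25 ± 0.31 and the collagenase Mmp8 by 3.08 ± 0.33. Of 12 measured monocyte markers, 9 rose, 12 adjusted over the list alone, including Ly6c2 (3.28 ± 0.35) and Hp, which encodes haptoglobin (3.20 ± 0.31). Camera called both lists, with adjusted p = 2.4e-24 for neutrophils and 6.7e-18 for monocytes; with an estimated correlation these were adjusted p = 0.0536 and 0.0532. Markers of erythrocytes had a median log2 change of 0.34 over 6 genes, with no call (adjusted p = 0.822).

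Type I interferon genes rose with age in wild type: 16 of 32 passed, 22 adjusted over the list alone, with a median of 1.44. Ifi207, an interferon-induced DNA sensor family member, rose by 2.88 ± 0.29 and the antiviral gene Oasl2 by 1.98 ± 0.26. Homeostatic microglial genes fell, 13 of 22 over all genes and 17 adjusted over the list alone, with a median of -0.36. Siglech changed by -0.67 ± 0.09, the lipid receptor Gpr34 by -0.81 ± 0.12 and the purinergic receptor P2ry12 by -0.49 ± 0.09. Both lists were called by camera (adjusted p = 3.4e-16 and 8.8e-12), and with an estimated correlation had adjusted p = 0.116 and 0.0588. These lists moved in the same libraries as the neutrophil and monocyte markers.

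Genes of disease-associated microglia, a state seen around amyloid and in old brains, rose in 12 of 28 members and fell in 1 (14 and 1 adjusted over the list alone), with a median of 0.71. Lgals3, which encodes galectin, rose by 2.92 ± 0.29 and the lipid carrier Apoe by 0.80 ± 0.14, while the lipid-sensing receptor Trem2 fell (-0.57 ± 0.11). Glycolysis genes rose in 11 of 26 members and fell in 1 (14 and 1 adjusted over the list alone), with the glucose transporter Slc2a3 at 2.21 ± 0.25 and pyruvate kinase Pkm at 1.09 ± 0.11. Complement and phagocytic receptor genes rose in 9 and fell in 1 of 24 (9 and 3 adjusted over the list alone), including properdin Cfp (3.70 ± 0.44) and C3 (3.03 ± 0.41). Antigen presentation genes rose in 8 and fell in 1 of 24 (9 and 1 alone), with the class II chaperone Cd74 at 1.41 ± 0.22 and the co-stimulatory ligand Cd86 at -0.67 ± 0.12. Inflammatory cytokine genes rose in 5 of 29 (7 alone), including Il1b (2.81 ± 0.45) and its antagonist Il1rn (2.41 ± 0.39). Camera called these lists with adjusted p from 1.6e-09 to 0.0107, and with an estimated correlation adjusted p was 0.116 for disease-associated microglia, 0.116 for glycolysis, 0.322 for complement, 0.276 for antigen presentation and 0.124 for inflammatory cytokines. Without aged wild type replicate 1 the complement list was not called. The neutrophil and monocyte markers rose between the same libraries, and these lists were not separated from them.

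Cell cycle genes rose in 7 of 28 members (10 adjusted over the list alone) and immediate early and handling-stress genes in 6 of 24, with 1 fallen (13 and 1 alone). The mitotic motor Kif11 rose by 1.79 ± 0.38 and the early response gene Ier2 by 1.62 ± 0.29. Neither these lists nor those below were separated from the neutrophil and monocyte markers, which rose between the same libraries. Ependyma and choroid plexus markers rose in 2 of 6 (6 alone; median 1.97), border macrophage markers in 2 of 10 (3 alone) and pericyte and smooth muscle markers in 1 of 4 (3 alone). These 5 lists had, with an estimated correlation, adjusted p = 0.267, 0.161, 0.156, 0.116 and 0.156 in that order. Smaller called shifts were found for the nuclear-encoded oxidative phosphorylation list (median 0.26, 4 of 72 rose, 0 alone), the cytosolic ribosomal proteins (0.18, 4 of 76, 2 alone) and the tricarboxylic acid cycle (0.16, 4 of 26, 4 alone). Their adjusted p with an estimated correlation was 0.276, 0.554 and 0.322. Single libraries ended calls of 4 of these lists. Without aged wild type replicate 1 neither oxidative phosphorylation nor ribosomal proteins were called, and the ribosomal median was 0.0111. The ribosomal call also ended without young wild type replicate 3, the pericyte call without aged wild type replicate 2, and the tricarboxylic acid cycle call without young wild type replicate 1 or 2 or aged wild type replicate 3. Camera did not call the other 15 lists, with medians from -0.66 to 0.90: among them lysosome genes had a median of -0.03, T and NK cell markers -0.66, B cell markers -0.64 and cholesterol synthesis genes 0.22.

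In all, 1394 of 16086 genes passed in aged against young wild type, 1034 higher and 360 lower. Phldb2 (5.24 ± 0.74), the metalloreductase Steap4 (5.26 ± 0.97) and the neuropeptide receptor family member Mrgpra2b (4.96 ± 0.79) were among the largest rises, and the orphan receptor Gpr165 (-1.68 ± 0.20) and the guidance ligand Sema6d (-1.57 ± 0.30) among the largest falls. The granule enzymes Elane (5.93 ± 1.32) and Mpo (5.90 ± 1.41) had larger fitted rises, but their adjusted p reached 0.109 and 0.110 with a library left out. Groups did not overlap in 26.2% of genes, against 10% by chance. Leaving out young wild type replicate 2 gave 860 genes, aged wild type replicate 1 gave 781 and aged wild type replicate 3 gave 731; a fold of at least 2 gave 785 and limma without trend and robust gave 581, which ended the calls of P2ry12, Trem2 and Kif11. With the mean of the neutrophil and monocyte markers as a covariate, an alternative chosen after seeing the data, 0 genes passed by limma, the only tool run with it, and Trem1 was at 2.49 rather than 4.14. Group accounted for 92.2% of the variance of that mean, and standard errors grew 3.30-fold at the median. Log2 Trem1 minus that mean was 1.09 ± 0.21 (SE) higher in aged than in young wild type.

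**Figure D2:**
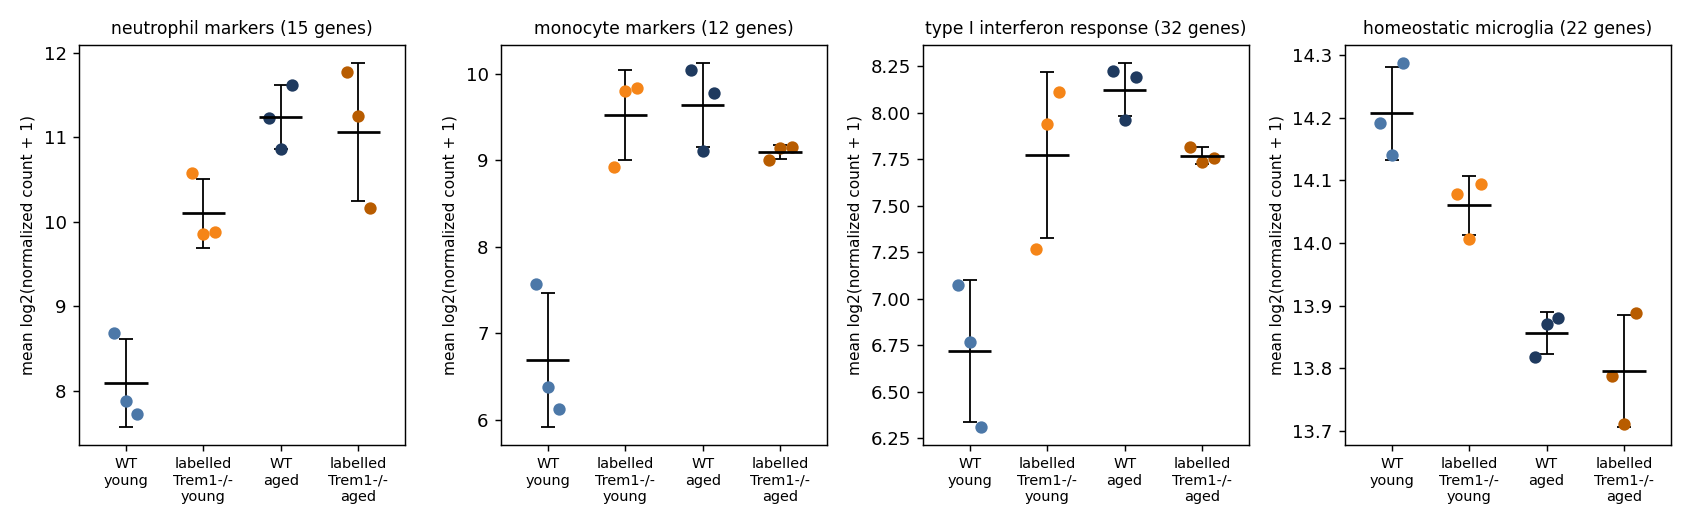
Mean log2(normalized count + 1) of the genes of 4 lists in each library of the aging table (points), with the group mean (line) and SD (bar), n = 3 per group; each panel has its own axis. Young wild type is lowest for the neutrophil, monocyte and interferon lists and highest for the homeostatic list.

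The second comparison set libraries labelled young Trem1-/- against young wild type, to ask what the deletion did in young microglia. Monocyte markers rose in 5 of 12 members (11 adjusted over the list alone), with a median of 2.72: Ly6c2 by 3.02 ± 0.35 (adjusted p = 1.0e-04) and Hp by 2.63 ± 0.31. Neutrophil markers rose in 4 of 15 (12 alone; median 1.66), including Cxcr2 (2.30 ± 0.31) and Retnlg (1.42 ± 0.26). Interferon genes rose in 9 of 32 (17 alone; median 1.05), including Ifi207 (2.61 ± 0.29) and Oasl2 (1.86 ± 0.26). Trem1 itself rose by 2.85 ± 0.45 (limma adjusted p = 6.2e-04). Camera called 14 of 32 lists; with an estimated correlation the monocyte list kept an adjusted p of 0.0167, while neutrophils had adjusted p = 0.0831 and interferon genes adjusted p = 0.157.

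Cell cycle genes rose in 7 of 28 in the libraries labelled young Trem1-/- (13 alone; median 1.41), with the mitotic motor Cenpe at 1.67 ± 0.31. Immediate early genes rose in 5 of 24 (12 alone), with the transcription factor Klf2 at 1.72 ± 0.29. Complement and phagocytic receptor genes rose in 4 of 24 (8 alone), with the scavenger receptor Msr1 at 2.68 ± 0.37 and Cfp at 3.13 ± 0.44. Ribosomal protein genes rose in 4 of 76 (7 alone; median 0.26), and 1 of 22 homeostatic genes fell (7 alone; median -0.18). Adjusted p with an estimated correlation was 0.171, 0.168, 0.171, 0.409 and 0.180 for these 5 lists in that order. Glycolysis, pentose phosphate, antigen presentation, lysosome and neuronal lists were called with medians of 0.20, 0.19, 0.13, 0.10 and -0.65. Each of these 5 lost its call with at least 1 library left out, and with an estimated correlation had adjusted p of 0.409, 0.180, 0.409, 0.591 and 0.182. Border macrophage markers rose in 2 of 10 (3 alone; median 0.95; adjusted p = 0.0833 with an estimated correlation). The neutrophil and monocyte markers rose between the same libraries, and these lists were not separated from them. With the mean of those markers as a covariate, chosen after seeing the data, the median was 0.03 for homeostatic, -0.10 for glycolysis and 0.09 for interferon genes, with median standard errors of 0.26, 0.40 and 0.83.

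Altogether 415 genes passed, 379 higher and 36 lower in the libraries labelled young Trem1-/-. Prtn3, a granule protease of myeloid precursors, rose by 4.77 ± 0.81, Wfdc17 by 4.97 ± 0.96 and the growth factor receptor Met by 4.33 ± 0.82; the splicing factor Srsf5 (-0.79 ± 0.12) and Apbb2, which encodes a protein that binds the amyloid precursor protein (-0.91 ± 0.17), fell. Groups did not overlap in 20.4% of genes, against 10% by chance. The count was 234 without young wild type replicate 2, 259 without young wild type replicate 3, 223 without labelled young Trem1-/- replicate 2 and 226 without its replicate 3; it was 649 with only the groups compared, 658 by DESeq2 and 97 by limma without trend and robust. With the neutrophil and monocyte covariate 0 genes passed and Trem1 was at 1.57 with no call. Limma without trend and robust ended the calls of Wfdc17, Prtn3, Met, Srsf5 and Apbb2, among others.

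In the third comparison, libraries labelled aged Trem1-/- were set against aged wild type, to ask whether the deletion changed old microglia. Trem1 differed by -0.55 ± 0.45 (adjusted p = 0.743), a difference near its standard error. By limma, 0 genes passed; 1545 had an unadjusted p under 0.05, the smallest adjusted p was 0.292, DESeq2 gave 29 genes and edgeR gave 0. Genes with the smallest p included the ribosomal protein gene Rpl38 at -1.41 ± 0.30, which did not pass. Groups did not overlap in 12.2% of genes, against 10% by chance. Leaving out aged wild type replicate 2 gave 15 genes and leaving out labelled aged Trem1-/- replicate 1 gave 5; no filter and a replicate block each gave 3, and limma without trend and robust gave 1.

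Camera called 12 lists in this comparison, 11 of them lower in the libraries labelled aged Trem1-/-, with no member past the threshold in any list. Ribosomal protein genes had a median of -0.23 (4 of 76 above 0), complement and phagocytic receptor genes -0.27, inflammatory cytokine genes -0.33 and lysosome genes -0.17. Adjusted over the list alone, 4 inflammatory genes, among them Tnf (-1.68 ± 0.45) and the adhesion gene Icam1 (-0.48 ± 0.13), 4 lysosome genes, 3 complement genes and 1 ribosomal protein gene were lower. Interferon genes had a median of -0.30, disease-associated genes -0.22, monocyte markers -0.37, antigen presentation -0.16, glycolysis -0.11, immediate early genes -0.25 and lipid efflux and droplet genes -0.16. Mitochondrially encoded genes were higher, with a median of 0.31 (11 of 13 above 0). With an estimated correlation none of the 12 kept its call, the smallest adjusted p being 0.170 for inflammatory cytokines, and fry kept that list only (adjusted p = 0.0415). Leaving out aged wild type replicate 1 gave 7 called lists, of which 6 were among these 12. Ribosomal, monocyte, glycolysis, lipid, immediate early and mitochondrially encoded genes then had no call. The interferon, disease-associated, inflammatory, lysosome and complement lists were called with each library left out.

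The fourth comparison asked what aging did in libraries labelled Trem1-/-. Lysosome genes fell in 9 of 29 members (20 adjusted over the list alone), with a median of -0.33: progranulin Grn by -0.56 ± 0.09 and the glucuronidase Gusb by -0.58 ± 0.12. Homeostatic microglial genes fell in 5 of 22 (10 alone), with the growth factor receptor Csf1r at -0.43 ± 0.07 and Fcrls at -0.57 ± 0.09. Complement and phagocytic receptor genes fell in 3 of 24 (12 lower and 1 higher alone), with C1qb, a subunit of the complement initiator, at -0.54 ± 0.10 and protein S, Pros1, at -0.51 ± 0.09. Apoe rose by 0.84 ± 0.14. Camera called the lysosome, homeostatic and complement lists (adjusted p = 1.1e-14, 2.8e-10 and 2.3e-08), and each had adjusted p = 0.159 with an estimated correlation.

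Neutrophil markers were higher as a list with age in the libraries labelled Trem1-/- (median 1.15), where 1 of 15 passed (3 alone): Retnlg at 1.40 ± 0.26, which lost its call without young replicate 2 or aged replicate 2. Monocyte markers had a median of -0.40 and interferon genes -0.03, with no call. Ependyma and choroid plexus markers were higher (median 2.26), where 1 of 6 passed (5 alone), as were neuronal (1.44) and astrocyte markers (0.44), each with 0 genes past the threshold over all genes. Ribosomal protein genes were lower (median -0.29; 3 of 76 fell, 6 alone), as were TREM receptor and DAP12 signalling genes (-0.21), and glycolysis genes were higher (0.17). With an estimated correlation adjusted p was 0.161 for neutrophils, 0.159 for choroid plexus, 0.159 for neurons, 0.161 for astrocytes, 0.304 for ribosomal proteins, 0.277 for TREM signalling and 0.483 for glycolysis. Leaving out aged replicate 3 ended the neuronal call and leaving out young replicate 2 or aged replicate 3 the astrocyte call; leaving out aged replicate 2 ended the TREM signalling call and aged replicate 1 the glycolysis call. Erythrocyte markers, at -0.57 with no call, were called at 0.921 in the other direction without aged replicate 2.

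Across all genes 275 passed, 173 higher and 102 lower in aged libraries labelled Trem1-/-. The membrane protein gene Tmem176a (-1.12 ± 0.16) and the glycosyltransferase Galnt12 (-0.92 ± 0.17) fell. Ptpn13 had the largest fitted rise (4.77 ± 1.07), with an adjusted p up to 0.103 with a library left out. Groups did not overlap in 21.2% of genes, against 10% by chance. With the neutrophil and monocyte covariate, chosen after seeing the data, 256 genes passed. The count was 94 without labelled young Trem1-/- replicate 2 and also without its replicate 3, 92 without labelled aged Trem1-/- replicate 2 and 182 without its replicate 3; DESeq2 gave 624, quantile normalization 121, a fold of at least 2 gave 156 and limma without trend and robust 12. The last of these ended the calls of all genes named as risen or fallen here; quantile normalization ended those of Csf1r and Pros1, and no filter those of Apoe and C1qb.

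The interaction tested whether the change with age differed between genotypes as labelled. It was lower in the libraries labelled Trem1-/- for 344 genes and higher for 64, 408 in all. The largest tests were for the actin-binding gene Tagln2 (-2.41 ± 0.27, adjusted p = 5.7e-05), the interferon-induced membrane gene Ifitm2 (-4.21 ± 0.49), the calcium-binding gene S100a11 (-2.85 ± 0.31), the sorting receptor Sorl1 (-1.83 ± 0.20) and the interferon-induced Slfn2 (-1.75 ± 0.21). Trem1 had an interaction of -3.40 ± 0.64 (adjusted p = 0.00429). Monocyte markers had a median of -2.90, with 4 of 12 past the threshold (11 alone), and interferon genes -1.39, with 9 of 32 (16 alone). Camera called 12 lists, all lower; with an estimated correlation the monocyte list kept an adjusted p of 0.0477 and the interferon list had adjusted p = 0.179.

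Young wild type was the lowest of the 4 groups for monocyte, neutrophil and interferon genes, and its 3 libraries enter the interaction and both comparisons with young wild type. Leaving out aged wild type replicate 2 gave 790 interaction genes; 197 passed without aged wild type replicate 3, 235 without its replicate 1 and 248 without young wild type replicate 2. Without labelled young Trem1-/- replicate 2 or 3 the counts were 251 and 203, and without labelled aged Trem1-/- replicate 2 or 3 they were 221 and 251. DESeq2 gave 813 genes, limma without trend and robust 5, with Tagln2 and Ifitm2 but not Trem1, S100a11, Sorl1 or Slfn2, and the neutrophil and monocyte covariate 0. Across 16086 genes the age change in wild type and the labelled Trem1-/- change in young microglia had r = 0.648, against 0.499 simulated for unchanged groups that share young wild type. Of the genes called, 348 were higher in both, against 24.4 for independent lists; the shared libraries raise this overlap by an amount that was not measured. Age change and labelled Trem1-/- change in aged microglia had r = -0.414, less negative than the -0.502 simulated for unchanged groups that share aged wild type, while their covariance of -0.273 was more negative than the simulated -0.200. The simulated groups hold no change with age, and a real change with age moves r toward 0 whatever the genotype does. The 2 values of r are therefore not alike, and their difference does not count against a reversal. The covariance is not moved in this way, but the spread of the simulated covariances is not given. Neither a reversal nor its absence can therefore be read from these values. Genes are not independent replicates, so these correlations carry no p.

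**Figure D3:**
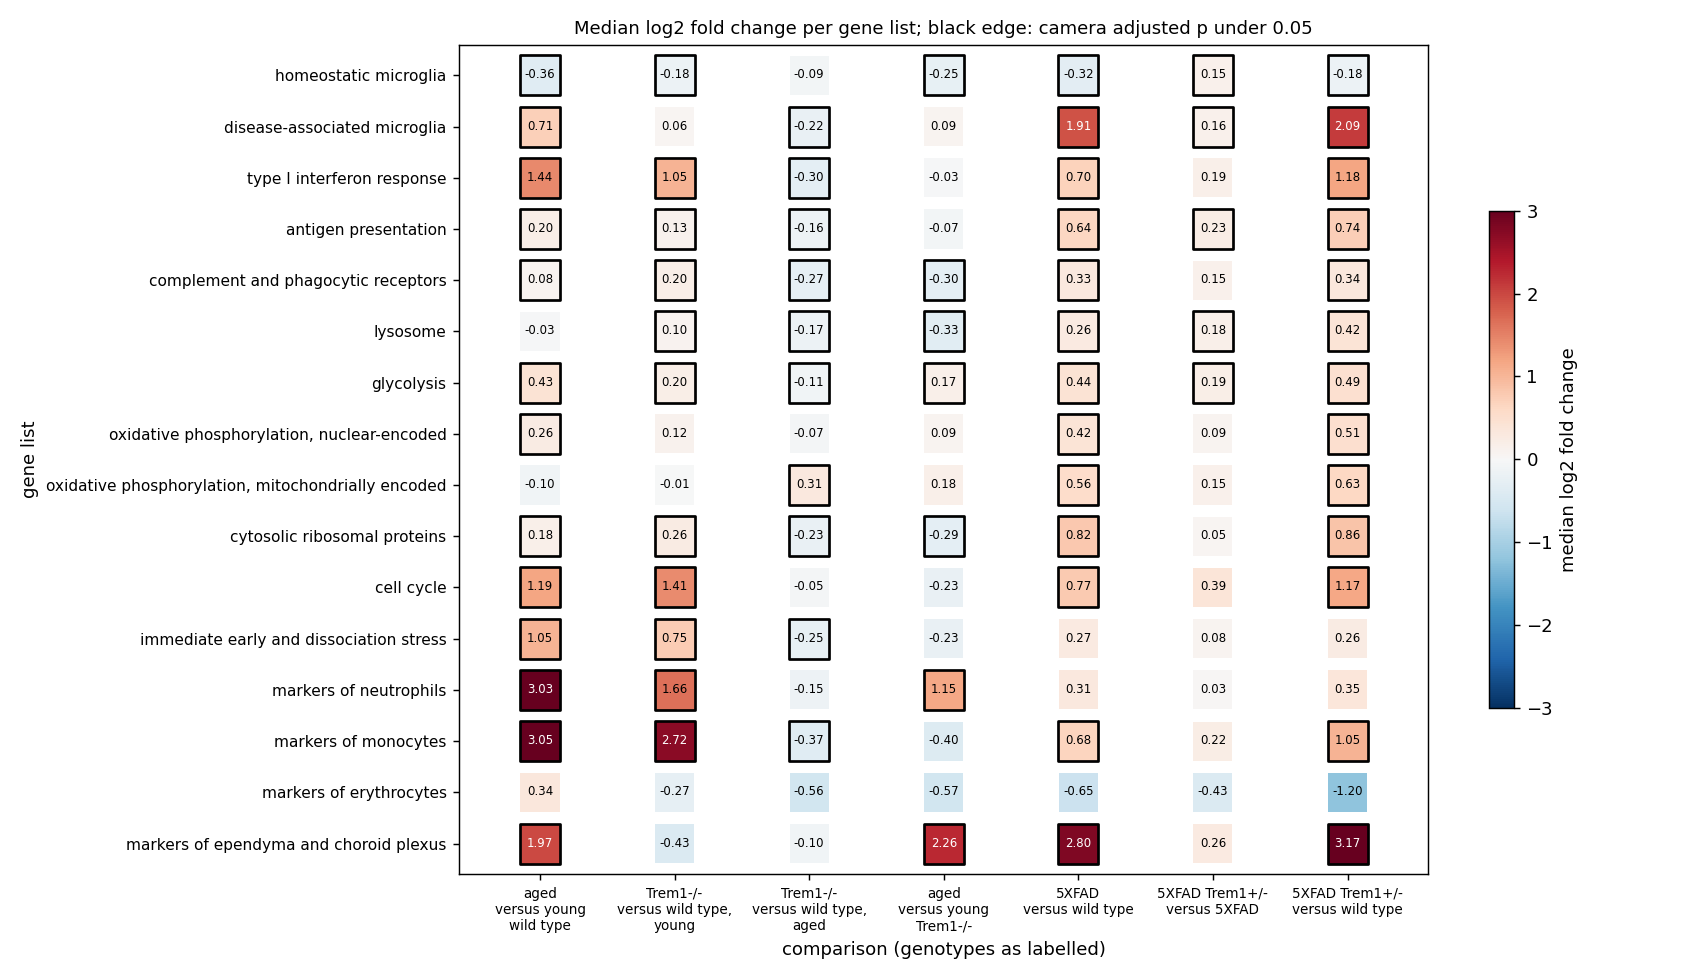
Median log2 fold change of 16 gene lists (vertical axis) in 7 comparisons (horizontal axis), coloured and printed; a black edge marks camera adjusted p under 0.05 at the preset correlation. The neutrophil and monocyte lists have medians of 3.03 and 3.05 in aged against young wild type, and disease-associated microglia 1.91 in 5XFAD against wild type.

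In the 5XFAD table, the comparison of 5XFAD with wild type asked what the amyloid model did to adult microglia. Genes of disease-associated microglia rose in 18 of 30 members, 28 adjusted over the list alone, with a median of 1.91 and all 30 above 0. The glycoprotein gene Gpnmb rose from 4.27 ± 7.40 to 446 ± 72.5 normalized counts (SD, n = 3), a log2 change of 7.53 ± 0.79 (adjusted p = 1.8e-04); of the wild-type libraries only replicate 3 had Gpnmb reads. Spp1, which encodes osteopontin, rose by 6.30 ± 0.82, the cysteine protease inhibitor Cst7 by 5.67 ± 0.41, the sterol hydroxylase Ch25h by 5.81 ± 0.70, Apoe by 3.22 ± 0.24, the receptor Clec7a by 2.38 ± 0.22 and the receptor tyrosine kinase Axl by 3.06 ± 0.29. Baiap2l2 was at 0 in wild type and at least 56.7-fold higher in 5XFAD. Camera called this list with adjusted p = 7.4e-45, and with an estimated correlation adjusted p = 0.0430; the median was the same with Baiap2l2 at its bound.

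Homeostatic genes fell in 4 and rose in 1 of 22 members (14 and 2 alone; median -0.32). The fractalkine receptor Cx3cr1 changed by -0.43 ± 0.08 and Siglech by -0.47 ± 0.09, which lost their calls without wild type replicate 2 and replicate 1 in that order. Fcrls rose (0.65 ± 0.13), with no call without wild type replicate 1 or 2. Glycolysis genes rose in 7 of 26 (12 alone; median 0.44), with Pkm at 0.99 ± 0.12, triosephosphate isomerase Tpi1 at 1.38 ± 0.19 and the hypoxia regulator Hif1a at 0.84 ± 0.13. Ribosomal protein genes rose in 21 of 77 (49 alone; median 0.82), with Rpl11 at 1.06 ± 0.18 and Rps18 at 1.68 ± 0.28. Lysosome genes rose in 4 of 29 (10 higher and 2 lower alone), with the protease Ctsl at 0.94 ± 0.15. Under an estimated correlation adjusted p was 0.0430 for glycolysis, 0.127 for homeostatic genes, 0.162 for ribosomal proteins and 0.342 for lysosomes.

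Nuclear-encoded oxidative phosphorylation genes rose in 6 of 72 members (20 alone; median 0.42) and mitochondrially encoded ones in 2 of 13 (5 alone; median 0.56). The mitochondrial ribosomal RNA mt-Rnr2 fell by 3.21 ± 0.10 on the log2 scale (adjusted p = 6.1e-14). It held 1.46% to 1.67% of reads in the 3 wild-type adult libraries and at most 0.209% in the other 18 libraries of both tables. Gm23935, annotated as a microRNA gene, held 2.75% to 3.34% in those libraries and at most 0.294% in the other 18, a feature singled out after its values were seen. Gm26917, the gene with the most reads in most libraries, held 1.27% to 1.91% against 1.07% to 4.84% and did not separate them. The shares of mt-Rnr2 and Gm23935 separate the wild-type adult libraries from every other library, and the labels name no batch, and a batch, if there was one, cannot be told apart from the group. Interferon genes rose in 3 of 30 (10 alone; median 0.70), antigen presentation genes in 2 of 24 (5 alone; 0.64), cholesterol synthesis genes in 1 of 22 (3 alone; 0.48), complement genes in 2 of 24 (3 alone; 0.33) and lipid efflux and droplet genes in 2 of 19 (7 alone; 0.29). Cell cycle genes had a median of 0.77 with none past the threshold, and 5XFAD replicate 3 carried the calls of the cell cycle and complement lists. With an estimated correlation adjusted p was 0.181 for each oxidative phosphorylation list and for interferon and antigen presentation genes, 0.162 for cholesterol synthesis, 0.393 for complement, 0.110 for lipid efflux and 0.499 for cell cycle.

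Markers of other brain cells were also higher in 5XFAD libraries. Astrocyte markers had a median of 2.23 (1 of 12 rose, 5 alone), neuronal markers 2.10 (1 of 13, 6 alone), ependyma and choroid plexus markers 2.80 (0 of 6, 4 alone) and oligodendrocyte precursor markers 2.72 (1 of 3, 1 alone). The synaptic kinase Camk2a rose by 2.18 ± 0.36 and the proteoglycan Cspg4 by 5.07 ± 0.92, though Cspg4 did not pass in edgeR. Border macrophage markers had a median of 0.98 and monocyte markers 0.68, and both calls ended without 5XFAD replicate 3. The monocyte call also ended without wild type replicate 2 or 3 or 5XFAD replicate 2, and the oligodendrocyte precursor call without 5XFAD replicate 1 or 3. Thy1, whose promoter drives the 5XFAD transgenes, rose from 0.367 ± 0.635 to 165 ± 183 normalized counts (SD, n = 3), and the 5XFAD mean was 59.5 without replicate 2; of the wild-type libraries only replicate 1 had Thy1 reads. Estimating the correlation gave adjusted p = 0.181 for astrocytes and choroid plexus, 0.0583 for neurons, 0.184 for oligodendrocyte precursors, 0.181 for border macrophages and 0.425 for monocytes. Lists without a call had medians from -0.65 to 1.27, including inflammatory cytokines (0.41), TREM receptor signalling (0.08), neutrophils (0.31, and -0.73 with a call without wild type replicate 2) and erythrocytes (-0.65).

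Over all genes 337 passed, 275 higher and 62 lower in 5XFAD. Cdc42ep1, an effector of the GTPase Cdc42, was at 0 in 5XFAD and at least 36.3-fold lower than in wild type; Gpr165 (-1.65 ± 0.27) and the transcription factor Klf7 (-1.10 ± 0.21) also fell. Groups did not overlap in 17.3% of genes, against 10% by chance. The count was 137 without wild type replicate 2, 134 without 5XFAD replicate 1 and 216 without 5XFAD replicate 2; it was 873 by DESeq2, 795 with no filter, 628 with a replicate block, 221 at a fold of at least 2 and 32 by limma without trend and robust. With the choroid plexus markers as a covariate, chosen after seeing the data, 45 genes passed. The calls of Gpnmb, Baiap2l2, Cst7, Ch25h, Apoe, Axl, Clec7a, Thy1 and mt-Rnr2 were kept under each alternative, the covariate among them. That of Cdc42ep1 was kept under all but the covariate (adjusted p = 0.0727), and limma without trend and robust ended those of Spp1, Pkm, Tpi1, Hif1a, Rpl11, Rps18, Ctsl, Camk2a, Gpr165 and Klf7.

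**Figure D4:**
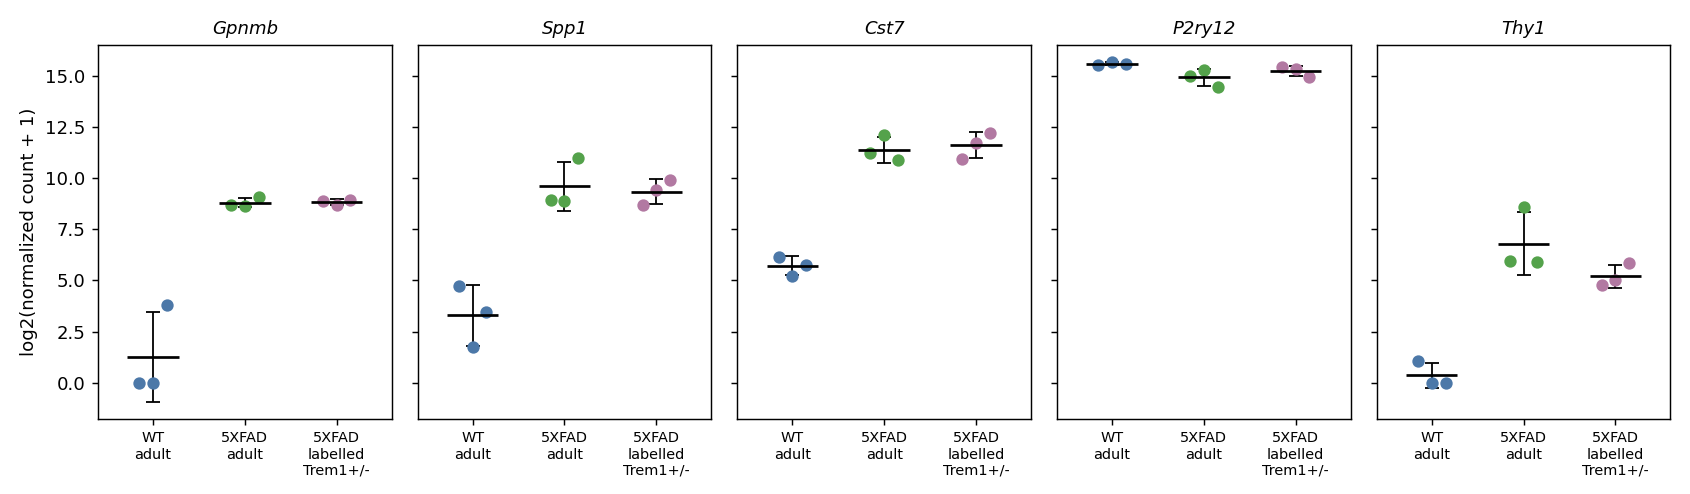
Level of 5 genes as log2(normalized count + 1) in each library of the 5XFAD table (points), with the group mean (line) and SD (bar), n = 3 per group. Gpnmb, Spp1, Cst7 and Thy1 sit higher in every 5XFAD library, with or without the Trem1+/- label, than in every wild-type library.

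**Figure D5:**
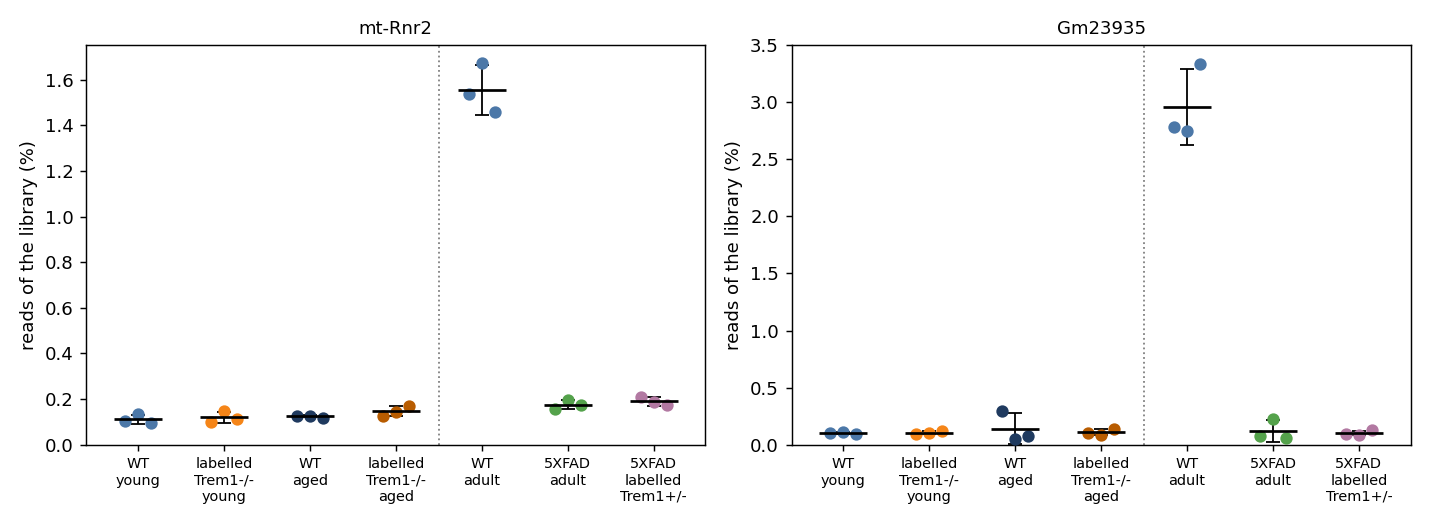
Share of reads on mt-Rnr2 and Gm23935 in each of the libraries of both tables (points), with the group mean (line) and SD (bar), n = 3 per group; the dotted line parts the tables. The 3 wild-type adult libraries hold 1.46% to 1.67% of reads on mt-Rnr2, above the other 18 libraries.

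Adult 5XFAD microglia labelled Trem1+/- were then compared with 5XFAD, to ask what loss of 1 Trem1 allele did in the amyloid model. Trem1 differed by 0.03 ± 1.23 (adjusted p = 0.997), with 27.2 ± 10.2 against 27.5 ± 12.2 normalized counts. Gpnmb was at 453 ± 40.1 against 446 ± 72.5 normalized counts and Cst7 at 3337 ± 1396 against 2858 ± 1316 (SD, n = 3). By limma, 0 genes passed; 883 had an unadjusted p under 0.05, the smallest adjusted p was 0.405, DESeq2 gave 30 genes and edgeR gave 0. Cdc42ep1 was at 0 in 5XFAD and at 66.1 ± 59.1 normalized counts (SD, n = 3) with the Trem1+/- label. That mean was at least 20.8-fold higher, a bound that covers the floor of 3 reads and not this spread. By limma the gene did not pass (adjusted p = 0.405). Groups did not overlap in 11.9% of genes, against 10% by chance; with no filter 29 genes passed, without 5XFAD replicate 1 there were 2 and without labelled Trem1+/- replicate 1 there was 1.

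Camera called 6 lists between labelled Trem1+/- and 5XFAD, with no member past the threshold over all genes. Homeostatic genes had a median of 0.15 (21 of 22 above 0) and lysosome genes 0.18 (24 of 29), each with 2 genes higher adjusted over the list alone, among them Siglech (0.37 ± 0.09) and the lysosomal receptor Scarb2 (0.32 ± 0.09). Antigen presentation (0.23), glycolysis (0.19) and disease-associated genes (0.16) were called higher and neuronal markers (-0.88) lower, each of which lost its call without 5XFAD replicate 3. The disease-associated call also ended without 5XFAD replicate 1 or labelled Trem1+/- replicate 2 or 3, the antigen presentation call without labelled Trem1+/- replicate 1, the glycolysis call without its replicate 3 and the neuronal call without its replicate 1 or 2. With an estimated correlation adjusted p was 0.444 for homeostatic genes, 0.824 for lysosomes and no smaller than 0.444 for any list, and fry called none. No filter gave 11 lists and quantile normalization 3. Across genes the 5XFAD change and the labelled Trem1+/- change had r = -0.388, against -0.502 simulated for unchanged groups that share 5XFAD, and -0.226 over genes with a mean of at least 50. Their covariance was -0.312, against -0.316 simulated. The simulated groups hold no 5XFAD change, and a real one moves r toward 0, so the measured and simulated r are not alike.

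Microglia from 5XFAD labelled Trem1+/- were also compared with wild type. Disease-associated genes rose in 20 of 30 members (29 alone; median 2.09; adjusted p = 0.0264 with an estimated correlation), with Gpnmb at 7.56 ± 0.79, Cst7 at 5.90 ± 0.41 and the integrin Itgax at 2.94 ± 0.26. The secreted protein gene Lgi2 rose by 7.66 ± 0.88 and the Wnt antagonist Dkk2 by 5.80 ± 0.94, and Baiap2l2 was at least 58.9-fold higher. Glycolysis genes rose in 7 of 26 (12 alone; adjusted p = 0.0240 with an estimated correlation), lysosome genes in 9 of 29 (17 alone), ribosomal protein genes in 28 of 77 (57 alone), antigen presentation genes in 4 of 24 (7 alone) and interferon genes in 4 of 30 (11 alone). Each of the last 4 lists had adjusted p = 0.137 with an estimated correlation. Camera called 22 lists, and 2 kept a call with an estimated correlation. The ribosomal RNA mt-Rnr2 fell by 3.05 ± 0.10, and ependyma and choroid plexus markers had a median of 3.17 (0 of 6 past the threshold, 5 alone). Neutrophil markers had a median of 0.35 with no call, and -0.499 with a call without wild type replicate 2.

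In total 473 genes passed, 347 higher and 126 lower in 5XFAD labelled Trem1+/- than in wild type, with no overlap in 25.5% of genes against 10% by chance. The count was 164 without wild type replicate 2, 275 without labelled Trem1+/- replicate 2 and 115 without its replicate 3. DESeq2 gave 1172 genes, no filter 952, a replicate block 848, a fold of at least 2 gave 297, the choroid plexus covariate 50 and limma without trend and robust 27, without Lgi2 and Dkk2. Across genes this change and that of 5XFAD had r = 0.724, against 0.501 simulated for unchanged groups that share wild type, and 206 genes were higher in both, against 5.60 for independent lists. The shared wild-type libraries raise this overlap too, by an amount that was not measured.

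The changes with age in wild type and in 5XFAD were set side by side, since they share no library. Ependyma and choroid plexus markers were higher as a list in both (medians 1.97 and 2.80), though neither call was kept with an estimated correlation. In 5XFAD no such marker passed over all genes. The wild-type adult libraries also stood apart in mt-Rnr2 and Gm23935, so the overlap below is not separated from either. Across 15657 genes tested in both tables, r was 0.367 and Spearman's rho 0.327. Of the genes called, 88 were higher in both, against 17.4 for independent lists, 22 were lower in both, against 1.43, and 3 went opposite ways, against 10.2. Apoe and Pkm rose in both and Gpr165 fell in both, genes chosen after their values were seen. Lgals3 was at 2.92 in aging and 1.19 in 5XFAD, where it did not pass (adjusted p = 0.316), and neutrophil markers at 3.03 and 0.31; the difference between the tables was not tested. Cst7, at 5.67 in 5XFAD, did not pass with age (adjusted p = 0.0859).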

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

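The interaction of age and genotype was among the comparisons fixed in advance; the counts over other splits of the libraries and the tests of labels, cell mixture and blood were chosen after the result was seen. The change with age differed between genotypes as labelled in 408 genes by limma, which is what singled these results out. For Trem1 the interaction was -3.40, for Tagln2 -2.41, for Ifitm2 -4.21, for S100a11 -2.85, for Sorl1 -1.83 and for Slfn2 -1.75 on the log2 scale. By camera 12 lists differed, with medians of -2.90 for monocyte markers, -1.85 for neutrophil markers, -1.39 for interferon genes, -1.27 for cell cycle, -1.08 for immediate early genes and -0.51 for ribosomal proteins. The medians were -0.43 for complement, -0.39 for inflammatory cytokines, -0.37 for disease-associated microglia, -0.34 for glycolysis, -0.27 for lysosomes and -0.21 for antigen presentation. With the correlation estimated only the monocyte list kept its call (adjusted p = 0.0477); the other 11 had adjusted p = 0.179, 0.179, 0.272, 0.184, 0.272, 0.179, 0.179, 0.189, 0.272, 0.272 and 0.272 in the order given. Of 100 splits of the 12 libraries, 1, the real split, gave as many as 408 genes, and the highest other gave 166. These splits shuffled age and genotype labels together, so they stand for no group difference of any kind. With the age change left inside the shuffled groups, they cannot exclude chance for an interaction. Nor can chance be excluded for the lists, where 23 of 100 splits gave at least 12 and the highest gave 19.

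In the comparisons of 3 with 3 libraries there are 10 splits, too few for a share under 0.05. Aged against young wild type called 1394 genes against 0 in the highest other split, and 17 lists against 18, with 2 of 10 splits at least as high. The libraries labelled young Trem1-/- gave 415 genes against 21 and 14 lists against 13. Aged libraries labelled Trem1-/- gave 0 genes by limma (1545 at an unadjusted p under 0.05, 29 by DESeq2, 0 by edgeR) against 2 for the highest other split of those with aged wild type; a count of 0 is reached by every split, so this comparison of splits decides nothing. This comparison gave 12 lists against 15, with 3 of 10. Aging in libraries labelled Trem1-/- gave 275 genes against 1 and 10 lists against 12, with 3 of 10.

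Trem1 was higher by 2.85 in the libraries labelled young Trem1-/- than in young wild type. Relative to the mean of 27 neutrophil and monocyte markers the difference was 0.48 ± 0.19 (SE), and 0.31 to 0.62 with a library left out. Its two-sided exact permutation p was 0.1, the smallest that 3 against 3 allows. More of these cells in those libraries may account for some or most of the rise, provided that their allele still yields counted reads. This also assumes that Trem1 keeps pace with the markers. In aged against young wild type Trem1 relative to them differed by 1.09 ± 0.21 (SE), so it need not. With the marker mean as a covariate Trem1 was at 1.57 ± 1.16 (SE), too wide to tell how much of the rise remains. An exchange of the labels of the young groups would put the deleted allele in libraries with as few as 7 Trem1 reads, above a floor of 3, and stays open. A transcript still made by the deleted allele could give the 100 or more reads in each library labelled aged Trem1-/-. There Trem1 relative to the markers differed by -0.22 ± 0.58 (SE) from aged wild type. That difference was 0.12, 0.01 and -0.78 without labelled replicate 1, 2 or 3, so its sign hung on single libraries. An exchange of the young labels would leave these aged reads unaccounted for, so these last 2 explanations do not exclude each other. Without values per exon neither can be decided. An effect of the deletion on how many such cells enter the brain was not tested apart from these.

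Of 27 measured neutrophil and monocyte markers, 26 had a log2 change over 1 in aged against young wild type, a count that restates the pattern and so cannot decide between more of these cells and other causes. Whole blood with red cells is argued against: erythrocyte markers differed by 0.33 ± 0.53, neutrophil markers by 3.14 ± 0.37 and monocyte markers by 2.95 ± 0.53 (SE, n = 3). Blood freed of red cells stays open, as do entry of these cells into the old brain and a difference in dissection, since the labels name no lysis, sort or gate; the most abundant markers were Ngp and S100a9, with 25343 and 17362 normalized counts in aged against 3236 and 2558 in young wild type. Of the 27 markers, 2 are also in another list and 25 had a mean of at least 10 in young wild type. Young libraries may hold such cells too, so whether the markers are unique to cells from blood cannot be read from this. Whether this share carries the interferon genes cannot be told apart from age, since with the marker mean as a covariate the interferon median went from 1.44 to 0.10 while its median SE went from 0.33 to 1.04.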

How the results depend on the processing

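The covariate alternatives and the fit without the farthest library (young wild type replicate 2 and adult wild type replicate 2) were chosen after the result was seen. Of values of named genes under an alternative, 8261 kept their side of the threshold, 1235 lost the call and 271 gained one. For single lists these were 4097, 264 and 177, and for Trem1 142 and 4 lost. Those that kept their side include values with no call whose sign turned, such as Trem1 in 5XFAD against wild type. Counts and lists are given in the order aged against young wild type, young and aged labelled Trem1-/- against wild type, aged against young labelled Trem1-/-, interaction, 5XFAD, labelled Trem1+/- against 5XFAD, and that against wild type; the cause was not tested unless stated. DESeq2 gave 658, 29, 624, 813, 873, 30 and 1172 genes from the second on. Limma without trend and robust gave 581, 97, 1, 12 and 5 genes in the aging table, and 32 and 27 in both comparisons with adult wild type. A fold of at least 2 gave 785, 156, 221 and 297 in comparisons 1, 4, 6 and 8, where the rule itself removes genes. No filter, which tests more genes, gave 3, 795, 29 and 952 genes in comparisons 3, 6, 7 and 8, and 19 and 11 lists in comparisons 5 and 7. A replicate block gave 3, 628 and 848 genes in comparisons 3, 6 and 8. Quantile normalization gave 121 genes in comparison 4 and 3 lists in comparison 7, and only the groups compared gave 649 genes in comparison 2.

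The neutrophil and monocyte covariate gave 0 genes in comparisons 1, 2 and 5, with 7, 4 and 3 lists and Trem1 at 2.49, 1.57 and -1.94. Standard errors grew 3.30-fold in comparison 1, since group and covariate overlap. In comparison 4 the same covariate left 256 genes, against 275 without it. No tool other than limma was run with the covariate. The choroid plexus covariate gave 45 and 50 genes in comparisons 6 and 8. Limma without trend and robust ended the Trem1 interaction call at -3.40. Without the farthest library there were 860, 234 and 248 genes in comparisons 1, 2 and 5, and 137 and 164 in comparisons 6 and 8. An estimated correlation left 0, 1, 0, 0, 1, 2, 0 and 2 lists. In the same order fry called 20, 7, 1, 7, 10, 9, 0 and 13 lists. The relation of 5XFAD and labelled Trem1+/- changes had r = -0.226 over genes with a mean of at least 50; that of age and 5XFAD had r = 0.509 there and a Spearman's rho of 0.327. The ribosomal median in comparison 1 stayed above 0 without aged wild type replicate 1 (0.0111, up to 0.262 with others left out), where only the sign of the uncalled test was reversed (adjusted p = 0.739). Directions turned for erythrocyte markers in comparison 4 without labelled aged Trem1-/- replicate 2 (0.921, down to -1.46), and neutrophil markers without adult wild type replicate 2 in comparisons 6 (-0.732, up to 1.18) and 8 (-0.499, up to 1.198).

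With 1 library left out, counts ran from 731 to 1612, 223 to 424, 0 to 15, 92 to 335, 197 to 790, 134 to 343, 0 to 2 and 115 to 446 genes. Trem1 ran from 3.85 to 4.65, 2.55 to 3.35, -0.87 to -0.39, 0.42 to 0.90, -3.91 to -3.11, -0.76 to 2.24, -0.39 to 0.29 and -0.72 to 2.27. Lists called ran from 15 to 19, 11 to 16, 7 to 16, 10 to 13, 12 to 17, 14 to 21, 5 to 9 and 20 to 24. Correlations ran from -0.556 to -0.345 for age against labelled Trem1-/- in aged microglia, from -0.530 to -0.302 for 5XFAD against labelled Trem1+/-, and from 0.278 to 0.388 for age against 5XFAD. Depth and spread limit small changes. In simulated data 13.4% of 1.5-fold changes were called in the aging layout and 7.46% in the 5XFAD layout. These shares are for genes with a mean of at least 50.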

Other observations

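The counts over other splits and the tests of ribosomal RNA were chosen after the result was seen. Several lists not described above were called by camera in 5XFAD microglia labelled Trem1+/- against wild type, all but the homeostatic list higher. None of them kept its call with an estimated correlation. Nuclear-encoded oxidative phosphorylation genes had a median of 0.51 (8 of 72 rose by limma, 15 adjusted over the list alone), among them Cox8a (1.18 ± 0.21), a subunit of cytochrome oxidase. Cholesterol synthesis genes had a median of 0.67 (2 of 22 rose, 5 alone), lipid efflux and droplet genes 0.51, complement genes 0.34, cell cycle genes 1.17 and tricarboxylic acid cycle genes 0.24. Homeostatic genes were lower at -0.18, though Fcrls rose (0.78 ± 0.13). Inflammatory cytokine genes (0.29), among them the chemokine Ccl3 (3.15 ± 0.50), lost their call without wild type replicate 1 or labelled Trem1+/- replicate 2. With the correlation estimated, adjusted p was 0.140, 0.137, 0.117, 0.194, 0.322, 0.249, 0.275 and 0.255 for these 8 lists in that order.

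Markers of other brain cells were also higher in 5XFAD labelled Trem1+/- than in wild type by camera: astrocytes (2.32), oligodendrocyte precursors (4.01), neurons (1.23), endothelium (0.68), monocytes (1.05) and border macrophages. None of these 6 calls was kept with the correlation estimated, where adjusted p was 0.140, 0.152, 0.137, 0.194, 0.272 and 0.186 in that order. The border macrophage call ended without wild type replicate 2 or 3 or labelled Trem1+/- replicate 1 or 2, the endothelial call without wild type replicate 1 or 3 or labelled Trem1+/- replicate 1, and the monocyte call without wild type replicate 2. Ttr, a carrier of thyroid hormone made by the choroid plexus, was at 3821 ± 1939 normalized counts (SD, n = 3) in wild type, 36957 ± 32802 in 5XFAD and 46374 ± 42369 in 5XFAD labelled Trem1+/-. Replicate 1 was the highest library of all 3 adult groups for Ttr and for the choroid plexus genes Kl, Folr1 and Clic6, and without it the Ttr means were 2841, 18235 and 22128 in that order of groups. The list of TREM receptors and DAP12 signalling had medians of -0.02 in aged against young wild type, 0.10 and -0.11 for labelled Trem1-/- in young and aged microglia, and -0.04 for labelled Trem1+/- in 5XFAD, none of them called. Circadian clock genes had medians from -0.04 to 0.15 over the 7 comparisons of groups, none called, and sex-linked genes were not called in any comparison. That list joins Xist with Y-chromosome genes, which differ between the sexes in opposite directions. Its lack of a call therefore does not show that sex was balanced. The sign of the median and the direction of the camera test differed only in lists without a call.

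In the 5XFAD table the 10 splits of 6 libraries are too few for a share under 0.05. Against wild type, 5XFAD called 337 genes against 0 in the highest other split and 19 lists against 12, and 5XFAD labelled Trem1+/- called 473 genes against 1 and 22 lists against 16. Labelled Trem1+/- against 5XFAD called 0 genes by limma (883 at an unadjusted p under 0.05, 30 by DESeq2, 0 by edgeR) against 11; every split reaches 0, so this comparison of splits decides nothing. The same comparison called 6 lists against 13, with 6 of 10 at least as high.

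Mitochondrial ribosomal RNA was lower in 5XFAD than in wild-type adult libraries, with mt-Rnr2 at most 0.209% of reads in the other 18 libraries and at least 1.46% in wild-type adults. The mitochondrially encoded protein genes had a median of 0.56, above 0, so as a list they were not lower in 5XFAD. Few of them passed, and the list was not called with an estimated correlation. It also rests on the same wild-type adult libraries, so it cannot decide whether 5XFAD microglia hold less mitochondrial RNA. A library batch or ribosomal RNA removal that differed for the wild-type adult libraries may be the source, since wild-type libraries of the aging table held at most 0.133%, but in the 5XFAD table it cannot be told apart from genotype. Gm26917, at 1.27% to 1.91% in wild-type adults against 1.07% to 4.84% in the other 18, did not separate them. If a batch or the removal is the source, other differences from wild-type adults could carry it too, and a biological effect of amyloid on this RNA stays untested.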
